A study of Mus musculus with 9 samples.

How the data were processed

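RNA-seq was done on ovaries of CD1 mouse embryos taken on embryonic day 16 and cultured for 24 hours with vehicle, recombinant human BMP2 at 50 ng/ml or estradiol-17β at 3.67 µM. Per the labels' protocols, total RNA was extracted with a Qiagen micro kit, samples with an RNA integrity number over 9 were used, and libraries were made with the Illumina TruSeq RNA v2 kit, which does not mark strand. The deposited values are whole-number read counts per gene, 1 table per library. The submitters' processing notes name TopHat2, HTSeq and DESeq2 and the genome build mm10, with no versions. The annotation and the strand setting of the counting are not given in the sources used here, so reads of overlapping or antisense genes, and of near-identical paralogs, cannot be separated. Per the values in the files, each table holds 23420 genes and 5 summary rows for reads given to no gene. These rows held 38.2% to 39.7% of a library's total, mostly reads that did not align uniquely (mean 24.2%) and reads in no gene (13.8% with vehicle, 13.6% with BMP2 and 14.6% with E2), and they were left out of library sizes and tests. The treatment of each library is not stated in a field of its own, so groups were inferred from the prefixes of the titles, 3 libraries to a group. E2 is spelled out in the series title, and B2 was taken as BMP2 and C as vehicle because the protocol names 3 conditions and the titles hold 3 prefixes. What C1 in every title stands for is not explained. Replicate numbers in the titles were not taken to pair libraries across groups.

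Counts as deposited were tested with edgeR 4.0.16 in R 4.3.3. Genes were kept by filterByExpr with its defaults (a minimum count of 10 and a minimum total of 15), which left 16360; 2602 genes had a count of 0 in all libraries. Library sizes were scaled by TMM factors, 1 robust quasi-likelihood model with a mean per group was fitted to all 9 libraries (6 residual degrees of freedom), and each pair of groups was tested with an F test. P-values were adjusted over all genes tested by the Benjamini-Hochberg method, and a gene was called at an adjusted p under 0.05. Log2 fold changes are edgeR's, and their standard errors are the size of the log2 fold change divided by the square root of F. Levels are TMM-normalized CPM with the SD over 3 libraries. Depths of 30418674 to 34320077 counts and the small spread between libraries let changes well below 1.5-fold pass. On simulated counts for the comparison of BMP2 with vehicle (16249 genes), 50 genes with a mean CPM of at least 1 were changed at each size. Of these, 38% changed 1.1-fold, 80% changed 1.2-fold, 96% at 1.5-fold and 100% at 2-fold were recovered. Of 16049 unchanged genes, 5 were called. The 200 changed genes were far fewer than the genes called in the data. The adjusted p depends on that share, so these rates need not hold for the data.

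The 36 lists of genes, for pathways and for cell types that the ovary could hold, were fixed before the data were examined, with 511 entries, of which 509 were found, 9 of them under an older symbol (Gm1564 for Meioc, Sc4mol for Msmo1 and Beta-s for an adult globin are examples). A list was tested when at least 4 members passed the filter, which 34 did, with limma 3.58.1 camera on log2 CPM (prior count 2) at a preset correlation of 0.01, adjusted over these lists. Camera with an estimated correlation and fry were run beside it, and the text gives each list's number of members called and the number called when adjusted over the list alone. Genes are named by a rule fixed at the same time: regulators and reporter genes of BMP2 and oestrogen signalling and of oocytes always, then, among called genes with a mean CPM of at least 1 in the higher group, no overlap of libraries between groups and a symbol not of a predicted gene, the 8 highest and 8 lowest log2 fold changes, then the 5 smallest p-values, then up to 4 called members of each list. The rule asks for about 30 genes per comparison, and examples from the lists take the number named past 30. Genes whose other groups are low, such as Prss22, Elane, Aqp8 and Mpo, enter by their higher group alone. Genes named outside the rule are said to be chosen after their values were seen. Coordinates are from GENCODE vM21 on GRCm38, which is mm10, and exon overlaps are shares of a gene's exon bases in that annotation.

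Each result was computed again with DESeq2 1.42.0, with median-ratio size factors, with no filter on low counts, with a mean CPM of at least 1, with only the groups compared, with the replicate number as a block, without each library in turn, and at other thresholds. A test against a change of 1.2-fold (glmTreat) and an offset that removes each library's trend on GC content and transcript length (splines with 5 degrees of freedom, for the 97.95% of tested genes with a GENCODE transcript) were chosen after seeing the data, as were 7 further lists. Comparisons that share the vehicle libraries were set beside 20 simulated draws of unchanged groups. All 9 libraries, vehicle included, were simulated from gene means over all groups, and both comparisons shared the simulated vehicle libraries. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15.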

Results

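Ovaries of CD1 mouse embryos were collected on embryonic day 16, when oocytes are still held in germ cell cysts and primordial follicles have begun to form or are about to, and were cultured for 24 hours. The medium held vehicle, recombinant human BMP2 at 50 ng/ml or the oestrogen estradiol-17β (E2) at 3.67 µM. BMP2 is a ligand of the TGFβ family that signals through SMAD1 and SMAD5. RNA from each group was sequenced in 3 libraries, 9 in all, and the values are read counts per gene. The counts of all genes summed to 30860223 to 34253992 per library with vehicle, 33360565 to 34320077 with BMP2 and 30418674 to 31778161 with E2 (n = 3 each), and 18953 to 19169 genes had at least 1 count. The labels do not say whether the 3 libraries of a group came from separate cultures or animals, so the p-values measure only the spread between these samples, which may be technical.

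Libraries of a group were close to each other, with correlations of log2 CPM (counts scaled to library size) of 0.9959 to 0.9967 within groups and 0.9913 to 0.9953 between groups. The first principal component (40.5% of the variance) set the E2 libraries apart from the others, and the second (14.7%) set BMP2 apart from vehicle. The spread beyond counting noise was small, with a biological coefficient of variation of 1.87%, yet every pair of libraries within a group differed by more than sampling noise (chi-square per gene 1.51 to 2.39). The 4 Y-linked genes examined, Ddx3y, Kdm5d, Eif2s3y and Uty, had 0 counts in all 9 libraries. Of 16360 genes tested with edgeR, 2239 differed between BMP2 and vehicle, 5278 between E2 and vehicle and 4607 between BMP2 and E2. Most of these differences were small, and 1772, 3348 and 2874 of them were below 1.2-fold.

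The comparison of BMP2 with vehicle asks which ovarian transcripts respond to this ligand during the day of culture. Nobox was 1.47-fold higher (13.0 ± 0.390 against 8.89 ± 0.580 CPM, mean ± SD, n = 3) and Lhx8 1.54-fold higher (log2 fold change 0.62 ± 0.066 SE), both genes for transcription factors that oocytes need to grow. The immediate early genes Fos, Fosb and Nr4a1 were 2.26-fold, 2.27-fold and 2.29-fold higher, with log2 fold changes of 1.17 ± 0.076, 1.18 ± 0.12 and 1.19 ± 0.084 (SE). All 7 tested genes of the ovarian surface epithelium and mesothelium were lower, among them Krt18 at 1.16-fold lower (log2 fold change -0.21 ± 0.032). Among the larger changes were genes of granulocytes at low abundance, with the azurophil granule gene Mpo 5.66-fold higher and the specific granule gene Ltf 4.77-fold lower. In all, 1119 genes were higher and 1120 lower with BMP2 at an adjusted p under 0.05, of which 79 and 69 differed by over 1.5-fold.

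All 4 fixed regulators of oocyte genes rose with BMP2. Lhx8 lies on chromosome 3 from 154306294 to 154330659 and Nobox on chromosome 6 from 43303674 to 43309554, both on the minus strand of GRCm38. Their log2 fold changes were 0.62 ± 0.066 (adjusted p = 3.3e-14) and 0.55 ± 0.074 (adjusted p = 7.9e-10). Sohlh1, which acts with Lhx8 and Nobox in oocytes, was 1.33-fold higher (log2 fold change 0.41 ± 0.050 SE, adjusted p = 1.3e-08), and Figla, needed for primordial follicles to form, 1.18-fold higher (log2 fold change 0.24 ± 0.049 SE, adjusted p = 1.0e-04). Of 15 oocyte differentiation genes tested, 5 rose and 10 did not pass (adjusted over the list alone, 5 rose and 1 fell). The list passed in the upward direction (adjusted p = 0.0337), but adjusted p = 0.322 with an estimated correlation. It also did not pass without BMP2 replicate 3 (adjusted p = 0.196), without vehicle replicate 2 (0.0578), with no filter on low counts (0.0746) or with the replicate number as a block (0.0703).

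Among 17 germ cell genes, 7 rose, 1 fell and 9 did not pass (adjusted over the list alone, 7 rose and 1 fell), and the list passed upward (adjusted p = 0.00775, but adjusted p = 0.141 with an estimated correlation). Dppa3 was 1.77-fold higher (log2 fold change 0.82 ± 0.080 SE, adjusted p = 3.8e-16) and Tdrd1, a gene of the piRNA pathway that silences transposons, 1.39-fold higher (log2 fold change 0.48 ± 0.036 SE, adjusted p = 2.1e-23). Ddx4, expressed throughout the germ line, rose by little (log2 fold change 0.12 ± 0.022, adjusted p = 1.4e-05), while Tex101 fell (-0.25). Tdrd9, another piRNA pathway gene and among the smallest p-values of the comparison, reached 165 ± 1.11 against 116 ± 1.03 CPM, 1.42-fold higher. Meiotic prophase genes moved the other way. Of 30 tested, 1 rose, 11 fell and 18 did not pass (adjusted over the list alone, 1 rose and 14 fell), and the list passed downward (adjusted p = 2.5e-04, but adjusted p = 0.176 with an estimated correlation). The recombinase gene Dmc1 was 1.23-fold lower (log2 fold change -0.30 ± 0.040 SE, adjusted p = 8.4e-10), and Stag3, a cohesin subunit of meiotic chromosomes, 1.11-fold lower (log2 fold change -0.15 ± 0.022). Smc1b, another meiotic cohesin gene, was the member that rose (log2 fold change 0.14 ± 0.019 SE, adjusted p = 4.0e-10).

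Direct readouts of BMP signalling changed by little. Id1, a standard target of SMAD1 and SMAD5, was 1.16-fold higher with BMP2 (175 ± 3.80 against 151 ± 2.18 CPM, log2 fold change 0.21 ± 0.023, adjusted p = 1.0e-13), and Id3 was also higher (log2 fold change 0.13 ± 0.028 SE, adjusted p = 1.6e-04). Id2 (log2 fold change 0.049 ± 0.025, adjusted p = 0.205), Smad6 (0.13 ± 0.070, 0.223) and Smad7 (0.063 ± 0.052, 0.491) did not pass. Of 17 BMP targets and feedback genes tested, 3 rose and 14 did not pass (adjusted over the list alone, 4 rose), and the list did not pass (adjusted p = 0.180). Among 15 BMP ligands, receptors and SMADs, 1 rose, 2 fell and 12 did not pass (adjusted over the list alone, 1 rose and 2 fell), with adjusted p = 0.820 for the list, whose test leaned downward while its median and mean lay above 0 (7.4e-04 and 0.025 log2). Bmp2 itself fell (log2 fold change -0.18 ± 0.040 SE, adjusted p = 3.2e-04). The list of TGFβ, activin and AMH signalling did not pass (adjusted p = 0.473, test upward, median 0.058, mean -0.020). Of its 17 members, 5 rose, 3 fell and 9 did not pass (adjusted over the list alone, 5 rose and 4 fell).

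Genes of the supporting cells went both ways. Of 18 pregranulosa cell genes, 5 rose, 5 fell and 8 did not pass (adjusted over the list alone, 5 rose and 8 fell), and the list did not pass (adjusted p = 0.628). Foxl2, the transcription factor that keeps the female fate of these cells, was 1.16-fold higher (log2 fold change 0.21 ± 0.034 SE, adjusted p = 5.1e-07), and Lgr5, a marker of cortical pregranulosa cells, 1.08-fold lower (log2 fold change -0.11 ± 0.022 SE, adjusted p = 8.7e-05). Kitl, whose product binds KIT on oocytes, was 1.04-fold higher (1016 ± 7.51 against 978 ± 29.2 CPM, adjusted p = 0.0139). That call was lost without BMP2 replicate 3 (adjusted p = 0.0779), without vehicle replicate 1 (0.0523) and without vehicle replicate 2 (0.224). All 7 tested genes of surface epithelium and mesothelium fell, also when adjusted over the list alone (list adjusted p = 6.9e-07, and adjusted p = 0.0224 with an estimated correlation). Krt8 and Krt7, keratins of simple epithelia, had log2 fold changes of -0.22 ± 0.024 and -0.25 ± 0.033, and Krt18 (log2 fold change -0.21 ± 0.032 SE, adjusted p = 8.3e-08) lies on chromosome 15 from 102028180 to 102032027.

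Of 12 immediate early genes, which are induced within minutes of many stimuli, 9 rose and 3 did not pass (adjusted over the list alone, 11 rose). The list rose with adjusted p = 3.8e-10, and adjusted p = 0.0147 with an estimated correlation. Fos, on chromosome 12 from 85473890 to 85477273, reached 16.1 ± 1.12 against 7.11 ± 0.217 CPM, and Egr1 was 1.44-fold higher (log2 fold change 0.53 ± 0.040 SE, adjusted p = 2.1e-23). Cell cycle genes fell as a list (adjusted p = 1.7e-04, and adjusted p = 0.0396 with an estimated correlation), and of 25 tested, 10 fell and 15 did not pass (adjusted over the list alone, 1 rose and 12 fell). Top2a (-0.16) and Bub1 (-0.15) stood at 1.11-fold lower and 1.11-fold lower. Cholesterol biosynthesis fell too (adjusted p = 4.0e-04, and adjusted p = 0.0396 with an estimated correlation), and of 20 genes 1 rose, 9 fell and 10 did not pass (adjusted over the list alone, 1 rose and 14 fell). Lss and Idi1, enzymes of sterol and isoprenoid synthesis, had log2 fold changes of -0.19 ± 0.036 and -0.16 ± 0.028. Of 11 interferon response genes, 3 rose and 8 did not pass (adjusted over the list alone, 3 rose), and the list passed upward (adjusted p = 0.0120, but adjusted p = 0.130 with an estimated correlation). Of 20 oestrogen-responsive genes, 2 rose, 6 fell and 12 did not pass (adjusted over the list alone, 2 rose and 6 fell), and the list did not pass (adjusted p = 0.0519). Ltf and Lcn2, which are also specific granule genes, were among the 6 that fell (list median -0.024 and mean -0.24 log2). Greb1, an early oestrogen target, was higher with BMP2 (log2 fold change 0.27 ± 0.026 SE, adjusted p = 1.8e-15).

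The genes with the highest fold changes were of low abundance. Prss22, a serine protease, was 13.7-fold higher on total counts of 120 with BMP2 and 8 with vehicle over 3 libraries each, and Tmprss11a, also a serine protease, was 3.22-fold higher. Mpo and Elane, enzymes of the azurophil granules made by young neutrophil precursors, were 5.66-fold higher and 4.53-fold higher (log2 fold changes 2.50 ± 0.25 and 2.18 ± 0.34), and Mpo shares 15% of its exon bases with an antisense gene. Ltf, Ngp, Lcn2 and Chi3l3, which later neutrophil stages or macrophages make, fell, with log2 fold changes of -2.25, -2.03, -1.68 and -1.96, and Ltf stood at 2.26 ± 0.158 against 10.8 ± 0.797 CPM. Chi3l3 stood at 0.286 ± 0.218 against 1.13 ± 0.209 CPM, and without BMP2 replicate 2 its log2 fold change was -2.77. Stfa1 rose (log2 fold change 1.40) while its near copies Stfa2 (-1.21) and Stfa3 (-1.24) fell, and reads of these paralogs are uncertain. Cdh16, a cadherin of kidney and mesonephric tubules, was 2.50-fold lower, and Sprr1a, a gene of stratified epithelia, 2.30-fold lower. At higher abundance, Synj1 was 1.45-fold higher (252 ± 1.87 against 174 ± 2.38 CPM) and Adamts19 1.37-fold lower (178 ± 1.96 against 244 ± 3.84 CPM). DESeq2 called fewer genes, 710 higher and 676 lower. Against a change of 1.2-fold, a test chosen after the data were seen, 43 genes were higher and 27 lower.

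**Figure D1:**
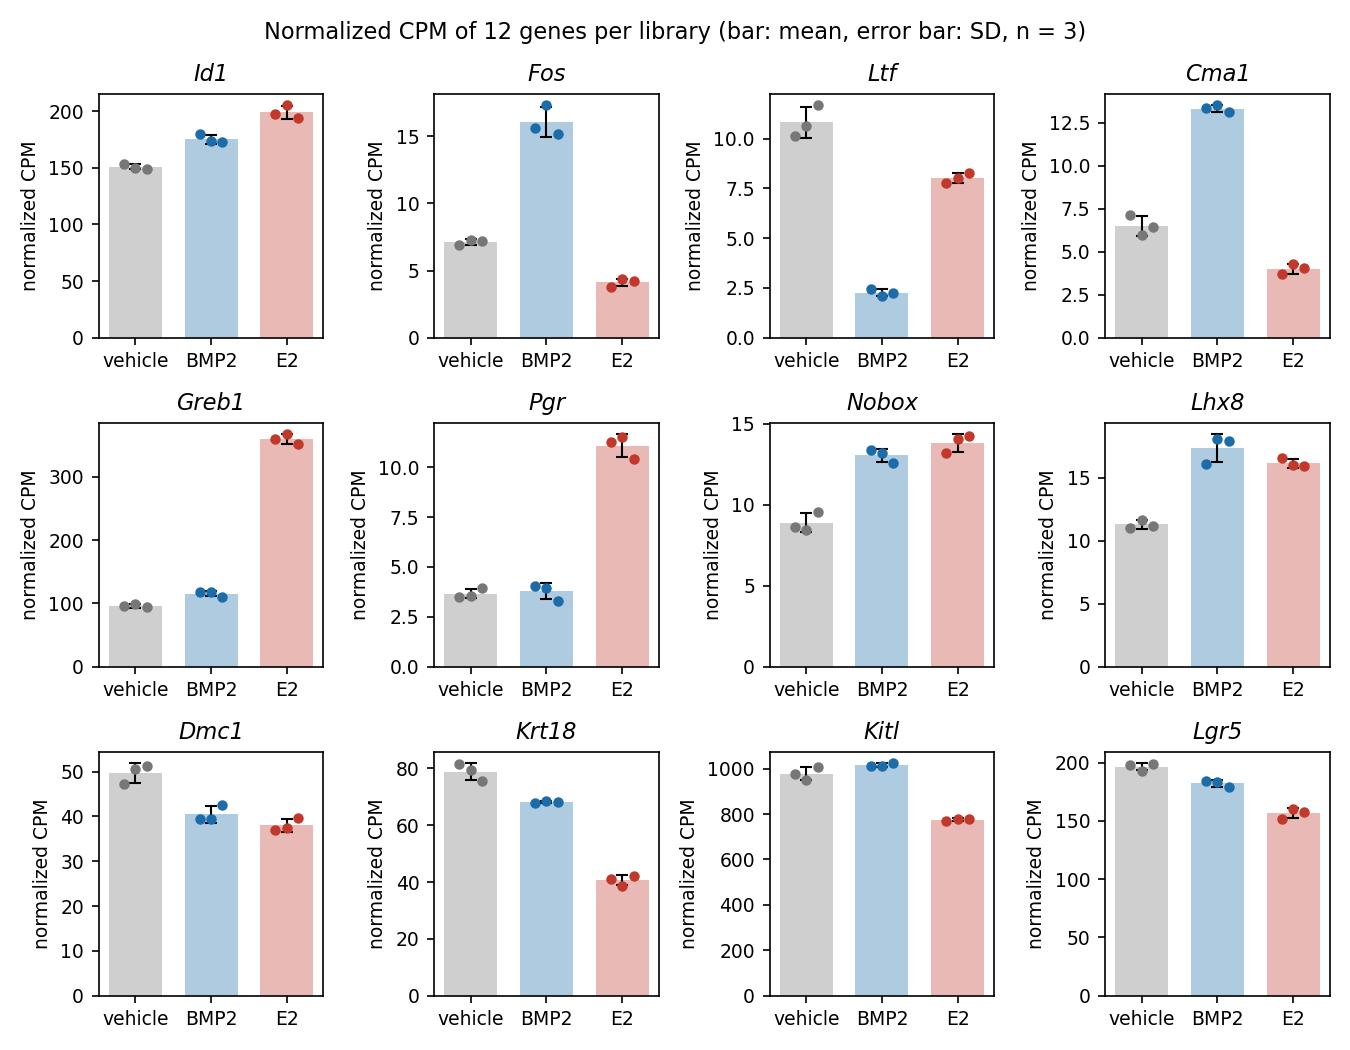
Normalized CPM of 12 genes in the 9 libraries, with bars for the mean of each group, error bars for the SD and points for single libraries (n = 3). Fos was higher with BMP2 and lower with E2 than with vehicle, Greb1 and Pgr were highest with E2, and Nobox and Lhx8 were higher with both treatments.

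The comparison of E2 with vehicle asks which transcripts of the fetal ovary respond to oestrogen. Some oestrogen targets rose, although the list of 20 oestrogen-responsive genes did not pass (adjusted p = 0.161). Greb1 was 3.75-fold higher with E2 (360 ± 7.60 against 96.2 ± 3.02 CPM, mean ± SD, n = 3) and Pgr, the progesterone receptor gene, 3.03-fold higher (11.1 ± 0.576 against 3.66 ± 0.233 CPM). Stc2, a secreted glycoprotein induced by oestrogen in other tissues, was 8.02-fold higher, and Oxtr, the oxytocin receptor gene, 8.59-fold higher. The oocyte gene Nobox was 1.55-fold higher and the meiotic gene Dmc1 1.31-fold lower. The keratin gene Krt18 was 1.94-fold lower (log2 fold change -0.96 ± 0.036 SE). E2 changed more genes than any other contrast, with 2577 higher and 2701 lower at an adjusted p under 0.05, of which 451 and 260 differed by over 1.5-fold.

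Greb1 lies on chromosome 12 from 16670615 to 16800886 and Pgr on chromosome 9 from 8899833 to 8968611. Their log2 fold changes were 1.91 ± 0.024 (adjusted p = 1.4e-106) and 1.60 ± 0.099 (adjusted p = 8.0e-32), and an antisense gene covers 7.68% of the exon bases of Greb1. Stc2, on chromosome 11 from 31357307 to 31370074, reached 27.5 ± 0.575 against 3.42 ± 0.473 CPM. Across the 20 oestrogen-responsive genes tested, 7 rose, 3 fell and 10 did not pass (adjusted over the list alone, 8 rose and 4 fell), and the list did not pass (adjusted p = 0.161). Nrip1, a corepressor of nuclear receptors that oestrogen induces, was 1.58-fold higher (log2 fold change 0.66 ± 0.035 SE, adjusted p = 2.7e-37). Of the receptors, Esr1 (log2 fold change 0.096 ± 0.041, adjusted p = 0.0595) and Esr2 (0.097 ± 0.13, 0.606) did not pass, although Esr1 did without vehicle replicate 2 (adjusted p = 0.0183), with the filter at a mean CPM of 1 (0.0497) and with the replicate number as a block (0.0494). Of 18 steroidogenesis genes and receptors, 7 rose, 4 fell and 7 did not pass (adjusted over the list alone, 8 rose and 4 fell), and the list did not pass (adjusted p = 0.267). Nr5a2, a nuclear receptor, was 1.84-fold higher and Hsd3b1, which makes progesterone and androgen precursors, 1.36-fold higher, while Star, which carries cholesterol into mitochondria, was 1.41-fold lower.

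Among the genes with the highest fold changes, Aqp8, a water channel, was 12.8-fold higher on total counts of 176 with E2 and 14 with vehicle. Asic4 (10.9-fold), an ion channel gene of which an antisense gene covers 18.1%, Wif1 (8.08-fold), an inhibitor of WNT ligands, Trpc4 (7.92-fold), a cation channel, Gpr35 (6.47-fold) and Dpp6 (6.18-fold) were also higher. At higher abundance, Myh11, a smooth muscle myosin, was 3.39-fold higher (log2 fold change 1.76 ± 0.028 SE, adjusted p = 6.2e-101), Hunk, a kinase, 2.86-fold higher, Ltbp1, which binds latent TGFβ, 2.42-fold higher, and Igfbp5 1.54-fold higher (log2 fold change 0.62 ± 0.015). Of the other pericyte and smooth muscle genes 7 did not pass and 1 fell, of 9 tested, with the same counts adjusted over the list alone, and the list did not pass (adjusted p = 0.523). Pdyn, which encodes opioid peptides, was 2.86-fold lower, the neurofilament gene Nefm 2.80-fold lower, with 19.2% of its exons overlapped by Nefl, and Sfrp5, a WNT antagonist, 2.56-fold lower. Angptl7 was 2.65-fold lower (6.19 ± 0.190 against 16.4 ± 0.0859 CPM), and C1rb, Slco1a5 and Kctd8 were 2.62-fold, 2.57-fold and 2.56-fold lower.

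Of 15 oocyte differentiation genes, 8 rose, 1 fell and 6 did not pass (adjusted over the list alone, 8 rose and 1 fell), and the list passed upward (adjusted p = 0.0273, but adjusted p = 0.197 with an estimated correlation). Nobox (log2 fold change 0.64 ± 0.074 SE, adjusted p = 4.3e-13), Lhx8 (0.52 ± 0.068), Sohlh1 (0.52 ± 0.050) and Figla (0.24 ± 0.049) rose, and Nlrp5, a maternal effect gene, was 1.63-fold higher. With no filter on low counts the list gave adjusted p = 0.0592, and with the trend on GC content and length removed 0.0601. Of 17 germ cell genes, 7 rose, 1 fell and 9 did not pass (adjusted over the list alone, 7 rose and 1 fell), and the list passed upward (adjusted p = 0.0273, but adjusted p = 0.170 with an estimated correlation). It was lost without vehicle replicate 1 (adjusted p = 0.0626) and with the GC and length trend removed (0.0830). Dppa3 was 1.87-fold higher, Tdrd1 1.46-fold higher, Kit, the receptor for KITL, 1.26-fold higher, and Ddx4 1.07-fold higher (adjusted p = 1.9e-04). Meiotic prophase genes fell as a list (adjusted p = 6.2e-05, but adjusted p = 0.121 with an estimated correlation), and of 30 tested, 3 rose, 20 fell and 7 did not pass (adjusted over the list alone, 3 rose and 21 fell). Dmc1 (log2 fold change -0.39 ± 0.041 SE, adjusted p = 3.2e-15) and Prdm9, which marks recombination sites (log2 fold change -0.38 ± 0.036 SE, adjusted p = 7.6e-18), were among those that fell, and Smc1b (0.17 ± 0.019) was among those that rose.

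In the supporting cells, of 18 pregranulosa cell genes, 7 rose, 6 fell and 5 did not pass (adjusted over the list alone, 8 rose and 6 fell). The list did not pass (adjusted p = 0.920, test upward, median 0.051, mean -0.016). Kitl was 1.26-fold lower with E2 (776 ± 4.91 against 978 ± 29.2 CPM, log2 fold change -0.33 ± 0.017 SE, adjusted p = 6.8e-40) and Lgr5 1.26-fold lower (log2 fold change -0.33 ± 0.023 SE, adjusted p = 1.8e-27). Wnt4, which promotes ovarian fate, was 1.34-fold higher and Krt19 1.36-fold lower. Foxl2 (log2 fold change 0.080 ± 0.035, adjusted p = 0.0701) and Bmp2 (0.024 ± 0.040, 0.701) did not pass, but Foxl2 did without vehicle replicate 3 (adjusted p = 0.0364), without E2 replicate 1 (0.0276) and with the GC and length trend removed (0.00363). Inha and Inhbb, subunits of inhibin and activin, were 1.46-fold higher and 1.59-fold higher, in a list of 17 TGFβ, activin and AMH genes that did not pass (adjusted p = 0.205), where 5 rose, 2 fell and 10 did not pass (adjusted over the list alone, 5 rose and 2 fell). Of 17 BMP targets and feedback genes, 6 rose, 4 fell and 7 did not pass (adjusted over the list alone, 6 rose and 5 fell), and the list did not pass (adjusted p = 0.666), although Id1 was 1.32-fold higher with E2 (log2 fold change 0.40 ± 0.023 SE, adjusted p = 3.6e-34).

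All 7 surface epithelium and mesothelium genes fell with E2, also when adjusted over the list alone (list adjusted p = 4.3e-07, and adjusted p = 0.0370 with an estimated correlation), with Krt8 1.55-fold lower. Of 12 immediate early genes, 7 fell and 5 did not pass (adjusted over the list alone, 8 fell), and the list fell (adjusted p = 6.2e-04, but adjusted p = 0.103 with an estimated correlation). Fos was 1.72-fold lower and Atf3 1.64-fold lower. Of 7 cyclin-dependent kinase inhibitors, which slow the cell cycle, 5 fell and 2 did not pass (adjusted over the list alone, 5 fell), and the list fell (adjusted p = 0.00448, but adjusted p = 0.117 with an estimated correlation), with Cdkn1c 1.27-fold lower and 30.7% of its exons under an antisense gene. Cell cycle genes also fell (adjusted p = 0.0165, but adjusted p = 0.117 with an estimated correlation), and of 25 tested, 2 rose, 11 fell and 12 did not pass (adjusted over the list alone, 2 rose and 11 fell). Of 24 extracellular matrix genes, 4 rose, 13 fell and 7 did not pass (adjusted over the list alone, 4 rose and 13 fell), and the list fell (adjusted p = 0.00899, but adjusted p = 0.312 with an estimated correlation), with the collagen genes Col1a1 1.27-fold lower and Col3a1 1.25-fold lower. Of 20 cholesterol biosynthesis genes, 11 rose, 3 fell and 6 did not pass (adjusted over the list alone, 11 rose and 3 fell), and the list rose (adjusted p = 0.0185, but adjusted p = 0.117 with an estimated correlation). Of 17 Wnt genes, 1 rose, 9 fell and 7 did not pass (adjusted over the list alone, 1 rose and 9 fell), and the list fell (adjusted p = 0.0165, but adjusted p = 0.170 with an estimated correlation). With the GC and length trend removed, the Wnt list gave adjusted p = 0.0830.

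Markers of other cells moved as well. Of 10 endothelial genes, 8 rose, 1 fell and 1 did not pass (adjusted over the list alone, 9 rose and 1 fell), and the list rose (adjusted p = 0.00801, but adjusted p = 0.117 with an estimated correlation). Pecam1 was 1.24-fold higher and Emcn 1.35-fold higher, while Kdr, a receptor for VEGF, was 1.25-fold lower. Of 11 macrophage and leukocyte genes, 5 fell and 6 did not pass (adjusted over the list alone, 5 fell), and the list fell (adjusted p = 0.00981, but adjusted p = 0.117 with an estimated correlation), with Lyz2 1.18-fold lower. Of 6 erythroid genes, 4 rose and 2 did not pass (adjusted over the list alone, 4 rose), and the list rose (adjusted p = 0.0165, but adjusted p = 0.190 with an estimated correlation). Slc4a1, the anion exchanger of red cells, was 1.84-fold higher and Alas2, of which Apex2 overlaps 12.9%, 1.48-fold higher. Of 5 neural crest and glia genes, 2 fell and 3 did not pass (adjusted over the list alone, 2 fell), and the list fell (adjusted p = 0.0292, but adjusted p = 0.162 with an estimated correlation). The neural crest list was lost without E2 replicate 3 (adjusted p = 0.0645), with the filter at a mean CPM of 1 (0.102), with no filter (0.0533) and with the GC and length trend removed (0.0991). Against a change of 1.2-fold, 531 genes were higher and 346 lower with E2.

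**Figure D2:**
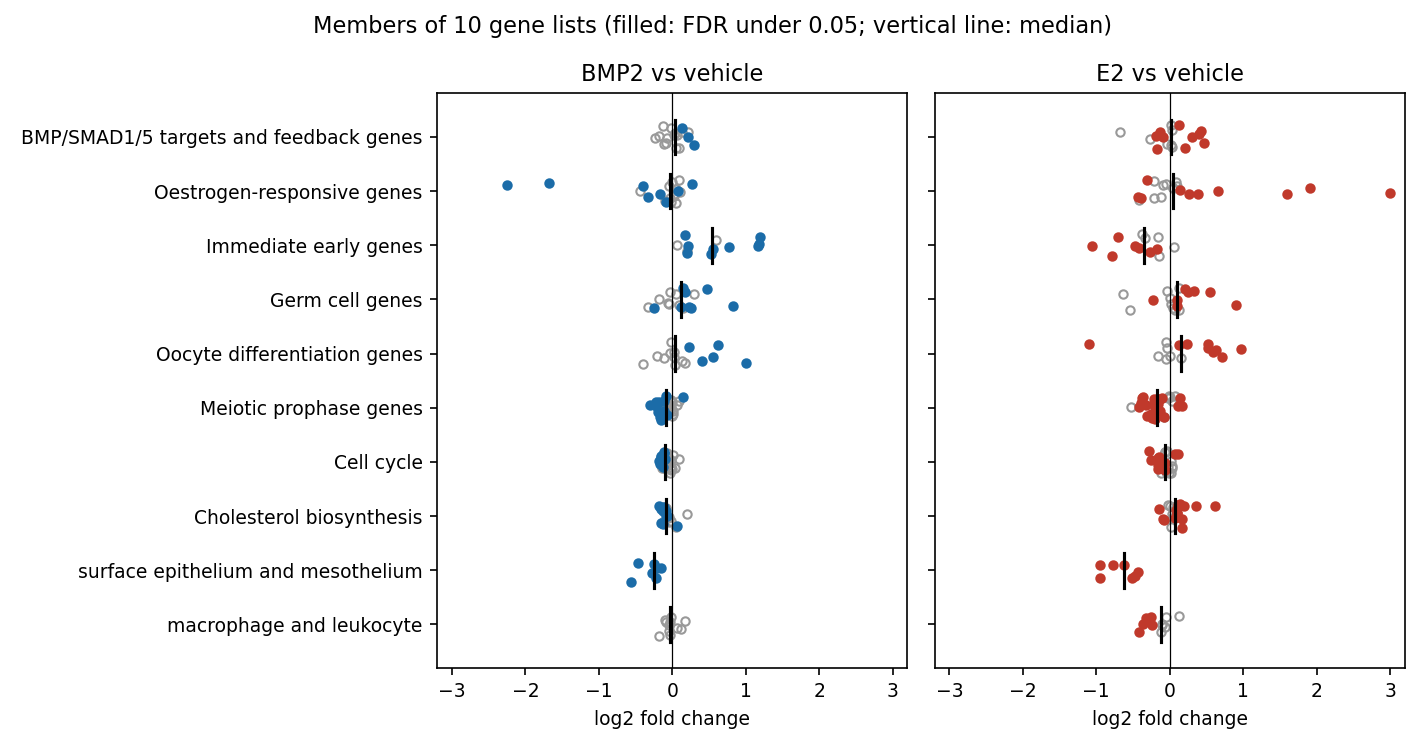
Log2 fold changes of the tested members of 10 gene lists against vehicle, BMP2 in one panel and E2 in the other, with filled points for an adjusted p under 0.05 and a vertical line at each list's median. The 7 surface epithelium genes lie below 0 in both panels, and the 12 immediate early genes all lie above 0 with BMP2 and mostly below 0 with E2.

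The comparison of BMP2 with E2 sets both treatments against each other. Of 20 oestrogen-responsive genes 9 were lower with BMP2 and 1 higher, with Greb1 3.12-fold lower (116 ± 4.30 against 360 ± 7.60 CPM, n = 3) and Pgr 2.93-fold lower (3.77 ± 0.401 against 11.1 ± 0.576 CPM). Of 12 immediate early genes 11 were higher with BMP2, with Fos 3.89-fold higher (log2 fold change 1.96 ± 0.086) and Fosb 4.74-fold higher (2.25 ± 0.15). The mast cell proteases Tpsb2 and Cma1 were 3.82-fold higher and 3.32-fold higher. In total, 2310 genes were higher and 2297 lower with BMP2 than with E2, of which 235 and 428 differed by over 1.5-fold.

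Aqp8 was 20.5-fold lower with BMP2 than with E2 on total counts of 9 and 176, and Klk1, a kallikrein, 7.03-fold lower. Stc2, Wif1, Oxtr, Asic4, Trpc4 and Zfp750 had log2 fold changes of -2.90, -2.94, -2.88, -2.92, -2.73 and -2.73. Mpo and Elane were 10.2-fold higher and 13.2-fold higher (Elane by a log2 fold change of 3.73, and of 4.32 without E2 replicate 2), and Prg2, a granule protein of eosinophils and mast cells, 3.47-fold higher. Myh11 was 3.47-fold lower, Hunk 2.90-fold lower and Ltbp1 1.97-fold lower, while H19, an imprinted noncoding RNA, was 1.51-fold higher (3094 ± 15.8 against 2050 ± 18.5 CPM). Kitl was 1.31-fold higher with BMP2 (log2 fold change 0.39 ± 0.017 SE, adjusted p = 6.3e-47), Lgr5 1.17-fold higher, Foxl2 1.09-fold higher and Bmp2 1.15-fold lower, and the Foxl2 call was lost with the GC and length trend removed (adjusted p = 0.0538). Id1 was 1.14-fold lower (log2 fold change -0.18 ± 0.023 SE, adjusted p = 7.0e-12), Id2 higher (0.14), Smad7 1.15-fold higher and Esr1 1.13-fold lower. Id3 (log2 fold change 0.0083 ± 0.028), Smad6 (-0.072 ± 0.069) and Esr2 (0.20 ± 0.12) did not pass.

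For the regulators of oocyte genes no difference passed between the treatments. The log2 fold change was -0.0037 ± 0.048 for Figla (adjusted p = 0.968), -0.083 ± 0.069 for Nobox (0.404), 0.10 ± 0.062 for Lhx8 (0.221) and 0.021 ± 0.022 for Ddx4 (0.527), and Ddx4 passed with the GC and length trend removed (0.0483). Sohlh1 (-0.11 ± 0.047, adjusted p = 0.0779) passed without BMP2 replicate 2 (0.0469), vehicle replicate 2 (0.0221), vehicle replicate 3 (0.0255) or E2 replicate 3 (0.0301), with no filter (0.0322), with these groups alone (0.0170), with the replicate number as a block (0.0205) and with the GC and length trend removed (0.00150). Of 15 oocyte differentiation genes, 1 rose, 2 fell and 12 did not pass (adjusted over the list alone, 1 rose and 2 fell) (list adjusted p = 0.648), and of 17 germ cell genes, 3 fell and 14 did not pass (adjusted over the list alone, 2 fell) (list adjusted p = 0.861, test downward, median 7.2e-04, mean 0.032). Of 18 pregranulosa cell genes, 6 rose, 7 fell and 5 did not pass (adjusted over the list alone, 6 rose and 8 fell) (list adjusted p = 0.861, test downward, median -0.020, mean 0.012). Meiotic prophase genes were higher with BMP2 than with E2 as a list (adjusted p = 0.0200, but adjusted p = 0.309 with an estimated correlation), and of 30 tested, 11 rose, 2 fell and 17 did not pass (adjusted over the list alone, 12 rose and 3 fell). Without BMP2 replicate 3 the meiotic list gave adjusted p = 0.0620.

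Of 12 immediate early genes, 11 rose and 1 did not pass (adjusted over the list alone, 11 rose) with BMP2 relative to E2 (list adjusted p = 2.6e-09, and adjusted p = 0.0185 with an estimated correlation), with Egr1 1.94-fold higher and Nr4a1 2.55-fold higher. Of 20 cholesterol biosynthesis genes, 15 fell and 5 did not pass (adjusted over the list alone, 1 rose and 16 fell) (list adjusted p = 6.7e-06, and adjusted p = 0.0250 with an estimated correlation). Fdft1, of which Ctsb overlaps 18.3%, was 1.36-fold lower. Of 20 oestrogen-responsive genes, 1 rose, 9 fell and 10 did not pass (adjusted over the list alone, 3 rose and 11 fell) (list adjusted p = 4.8e-04, and adjusted p = 0.0392 with an estimated correlation), with Igf1 1.38-fold lower and Nrip1 1.52-fold lower. Ltf and Lcn2, which are also specific granule genes, were among the 9 that fell. Of 7 surface epithelium genes, 6 rose and 1 did not pass (adjusted over the list alone, 6 rose) (list adjusted p = 4.2e-05, and adjusted p = 0.0353 with an estimated correlation), with Krt18 1.67-fold higher. Of 24 extracellular matrix genes, 14 rose, 3 fell and 7 did not pass (adjusted over the list alone, 14 rose and 4 fell) (list adjusted p = 0.00305, but adjusted p = 0.309 with an estimated correlation), with Tnc 1.45-fold higher and Col3a1 1.33-fold higher. Of 11 macrophage genes, 4 rose and 7 did not pass (adjusted over the list alone, 4 rose) (list adjusted p = 0.0200, but adjusted p = 0.165 with an estimated correlation), with Tyrobp 1.35-fold higher. Of 7 cyclin-dependent kinase inhibitors, 4 rose and 3 did not pass (adjusted over the list alone, 4 rose) (list adjusted p = 0.0157, but adjusted p = 0.165 with an estimated correlation), and with the GC and length trend removed the list gave 0.0667. Against a change of 1.2-fold, 296 genes were higher and 488 lower with BMP2 than with E2.

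Other lists passed narrowly. Genes of the unfolded protein and integrated stress response were lower with E2 than with vehicle (adjusted p = 0.0467, but adjusted p = 0.197 with an estimated correlation), and of 12 tested, 1 rose, 5 fell and 6 did not pass (adjusted over the list alone, 1 rose and 5 fell). That result was lost without vehicle replicate 1 (adjusted p = 0.105), BMP2 replicate 1 (0.0505), BMP2 replicate 2 (0.0537) or E2 replicate 3 (0.0871), with these groups alone (0.0557), with the replicate number as a block (0.0529), with a mean CPM of at least 1 (0.0569) and with the GC and length trend removed (0.108). With BMP2 against E2 the same list was higher (adjusted p = 0.0269, but adjusted p = 0.219 with an estimated correlation), where 5 rose and 7 did not pass (adjusted over the list alone, 5 rose), and it was lost without BMP2 replicate 3 (0.0648), without E2 replicate 3 (0.0677) and with the GC and length trend removed (0.0695). Of 5 neural crest and glia genes, 2 rose and 3 did not pass (adjusted over the list alone, 2 rose) (list adjusted p = 0.0269, but adjusted p = 0.165 with an estimated correlation), and the list was lost without E2 replicate 3 (0.0520), with a mean CPM of at least 1 (0.133) and with the GC and length trend removed (0.200). Of 9 pericyte and smooth muscle genes, 4 fell and 5 did not pass (adjusted over the list alone, 1 rose and 4 fell) (list adjusted p = 0.0346, but adjusted p = 0.264 with an estimated correlation), and the list was lost with these groups alone (0.0523), with the replicate number as a block (0.0565) and without BMP2 replicate 3 (0.0576), vehicle replicate 3 (0.0551) or E2 replicate 3 (0.0520).

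Many genes were called in both comparisons with vehicle. Of the genes called in both comparisons, 549 were higher with both, 624 lower with both and 222 moved in opposite directions. Nobox, Lhx8, Dppa3 and Tdrd9 were among those higher with both, at log2 fold changes of 0.55, 0.62, 0.82 and 0.51 with BMP2 and 0.64, 0.52, 0.90 and 0.62 with E2. By list, 5 oocyte differentiation genes and 7 germ cell genes were higher with both, and 11 meiotic, 8 cell cycle and 7 surface epithelium genes lower with both. Opposite calls included 7 immediate early genes, with Fos at 1.17 with BMP2 and -0.79 with E2, and Adamts19 at -0.46 and 0.14. The 1395 genes called in both compare with 722 for independent calls (176 higher with both, 185 lower with both and 361 in opposite directions). Simulated unchanged groups against shared simulated vehicle libraries gave a mean of 0.2 and at most 1 over 20 draws. The vehicle libraries were simulated too, so an offset of the real ones cannot appear in these draws. The simulated groups hold no changed genes and the independent count leaves out the shared libraries, so neither shows how many genes respond alike to both treatments. Part of the excess of 1395 over 722 may come from the shared vehicle libraries, which are too few to be split into groups of at least 2. Log2 fold changes against vehicle rose with transcript length in both comparisons (Spearman correlation 0.128 with BMP2 and 0.107 with E2, 14213 genes). For BMP2 against E2 this correlation was -0.0180. With GC content the correlation was -0.0068 for BMP2 against vehicle, -0.161 for E2 against vehicle and 0.174 for BMP2 against E2. A length trend that both comparisons share can add to calls in the same direction. The count of opposite calls was 140 without vehicle replicate 1, and DESeq2 called 865 genes in both, 747 in the same and 118 in opposite directions. Against a change of 1.2-fold, 39 genes were called in both.

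Across the 16360 tested genes, which are not independent replicates, the log2 fold changes of BMP2 and E2 had a Pearson correlation of 0.306 and a Spearman correlation of 0.369, and 64.4% had the same sign. The Pearson correlation was 0.469 with no filter on low counts (20818 genes) and 0.453 with DESeq2. Both include low-count genes that the filter left out of the 16360. Unchanged groups against shared simulated vehicle libraries gave means of 0.497, 0.443 and 66.8%, above the values observed over the 16360 genes. The covariance was 0.0198 against a simulated 0.00921, a difference of 0.0106.

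**Figure D3:**
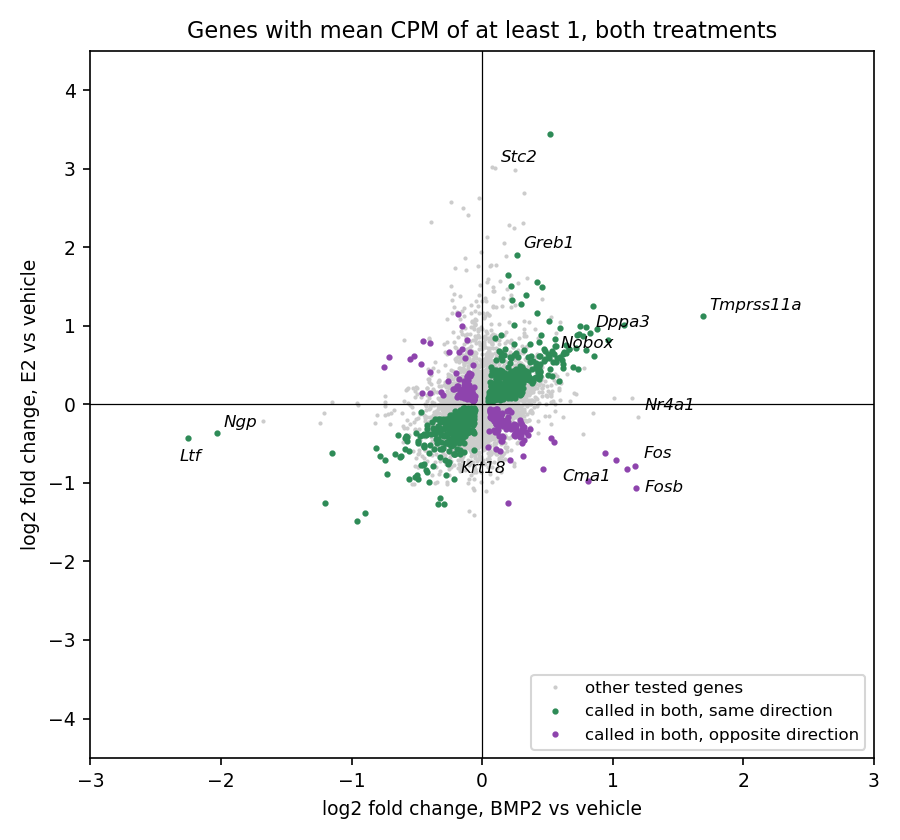
Log2 fold change against vehicle with E2 plotted against that with BMP2 for 14391 genes with a mean CPM of at least 1, with genes called in both comparisons in green for the same direction and purple for opposite directions, and other genes in grey. More genes lie in the same-direction quadrants, and 1 gene lies outside the axes. Of all tested genes 64.4% had the same sign, and simulated unchanged groups that share vehicle libraries gave a mean of 66.8%.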

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

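The tests of granulocyte number, of mast cell number, of germ cell share, of the vehicle ovaries and of the library spread were chosen only after the results were seen, as was the correction for GC content and length. Reads that lay in no gene were 14.6% ± 0.144 of all reads with E2 (SD, n = 3), above 13.8% ± 0.164 with vehicle in all 3 libraries, and they enter no comparison.

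In BMP2 against vehicle, 5 of 6 mast cell genes and 3 of 4 azurophil granule genes rose and 4 of 4 specific granule genes fell, with medians of 1.00, 1.66 and -1.85 log2 (adjusted p 5.1e-10, 1.2e-05 and 1.1e-09, and 0.00254, 0.00701 and 0.00254 with an estimated correlation), and of 7 mature neutrophil genes 2 fell and 5 did not pass (median -0.25, adjusted p 0.0249 downward, but 0.0973 with an estimated correlation). With E2 against vehicle, 4 of 6 mast cell, 1 of 4 azurophil and 3 of 4 specific granule genes fell, with medians of -0.67, -0.89 and -0.40 log2 (adjusted p 7.1e-04, 0.130 and 0.0178, and 0.0353, 0.183 and 0.0611 with an estimated correlation). Of 7 mature neutrophil genes, 2 fell and 5 did not pass with E2 (median 0.037, adjusted p 0.699, and 0.745 with an estimated correlation). All these lists were chosen after the values were seen. GC content and length are argued against, since all 12 called genes of the mast cell and granule lists stayed called with that trend removed. A different number of one kind of granulocyte cannot be told apart from changed expression, since the medians of azurophil and specific granule genes, 3.52 log2 apart, rest on lists in which 2 of 4 and 3 of 4 genes were among the largest changes that prompted them. More mast cells in the BMP2 ovaries before treatment cannot be told apart from a response of the same cells, since both raise the mast cell genes (median 1.00 log2, with the abundant Hdc up by 0.34 from 53.8 CPM and Cpa3 by 0.94 from 8.81 CPM), and an effect of BMP2 remains an open, untested explanation.

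Of 15 oocyte, 17 germ cell and 30 meiotic genes, 5 rose, 7 rose and 11 fell with BMP2 and 8 rose, 7 rose and 20 fell with E2, and all 6 list calls were lost with an estimated correlation (adjusted p 0.322, 0.141 and 0.176 with BMP2 and 0.197, 0.170 and 0.121 with E2). The BMP2 oocyte list was also lost without BMP2 replicate 3 (0.196) or vehicle replicate 2 (0.0578), and the E2 germ cell list without vehicle replicate 1 (0.0626). A changed share of germ cells alone would move all these genes one way. With BMP2, 11 meiotic genes fell while 12 of 32 oocyte or germ cell genes rose, and with E2 20 fell while 15 of 32 rose. These counts are the pattern that prompted the question, so they are no separate test of it. A changed share beside another change is left open. The trend on GC content and length is argued against as the whole cause, since 16 of 17 called genes of the oocyte and meiotic lists stayed called with BMP2 and 32 of 32 with E2, although the E2 oocyte and germ cell lists then missed the threshold (adjusted p 0.0601 and 0.0830), with medians going from 0.15 to 0.16 log2 (SD 0.50 in both) and from 0.097 to 0.069 (SD 0.36 and 0.35). Vehicle ovaries that differed from the start cannot be told apart from a like effect of both treatments. Only 4 of the 17 genes called in the same direction in both differed between BMP2 and E2, but these 17 were picked for moving alike. Of all 30 meiotic genes, 11 were higher and 2 lower with BMP2 than with E2 (list adjusted p = 0.0200, but 0.309 with an estimated correlation). Faster oocyte differentiation with each treatment is a candidate explanation that these data leave untested.

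Libraries of a group differed by little, and of 12714 genes with a mean count of at least 100 only 71 had a within-group range over 1.5-fold, against 401 whose group means lay over 1.5-fold apart. One library counted 3 times is argued against, since the lowest chi-square per gene of the 9 pairs was 1.51, above the 1 of sampling noise. One pool of RNA or tissue split into 3 libraries is consistent with the spread of 38 genes of rare blood and mast cells, whose median chi-square per degree of freedom (1.28, against 1.27 for matched lists) lay at the 54.1 percentile of 10000 matched lists. Small spread between pools of many ovaries would look alike, and no biological explanation was tested.

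For each comparison the 6 libraries can be split in 10 ways, too few for a share under 0.05. Each split but the real one mixes libraries of both groups, so a group difference adds to the spread within it. Few calls in those splits are therefore no measure of replicate noise. With edgeR, 1 of 10 splits, the real one, reached 2239 genes for BMP2 against vehicle, 5278 for E2 against vehicle and 4607 for BMP2 against E2, and the highest other split called 0 in each (978, 706 and 485 genes at an unadjusted p under 0.05, against 4164, 6614 and 6100 in the real split). Lists passing numbered 8, 15 and 11 in the real split and at most 5, 3 and 2 in the others, again 1 of 10 splits as large.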

How the results depend on the processing

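The test against a 1.2-fold change and the GC and length correction were chosen after the data were seen. Requiring a log2 fold change of at least 1 left 31 genes higher and 26 lower for BMP2 against vehicle, 189 and 48 for E2 against vehicle and 72 and 199 for BMP2 against E2. Testing against 1.2-fold gave 43 and 27, 531 and 346, and 296 and 488, with 39 genes called in both (28 in the same and 11 in opposite directions), and 239 of 427 named-gene values lost their call; here the stricter question is the cause. DESeq2 gave 710 and 676 for BMP2 against vehicle, 865 in both (747 and 118) and a fold change correlation of 0.453, and no filter gave a correlation of 0.469. Both correlations include low-count genes that the main filter left out, and the cause of these differences was not tested. With an estimated correlation 4, 1 and 4 lists passed and with fry 18, 29 and 21, in the same order. Without each library in turn, genes higher and lower ranged over 804 to 1127 and 824 to 1108 for BMP2 against vehicle, 2218 to 2637 and 2271 to 2679 for E2, and 1962 to 2398 and 1976 to 2450 for BMP2 against E2. Calls in both ranged over 1013 to 1378, same-direction calls over 873 to 1197, opposite calls over 140 (without vehicle replicate 1) to 204, lists over 7 to 10, 13 to 17 and 8 to 12, and the correlation over 0.285 to 0.396. Of BMP2 against E2, uncalled values changed sign without 1 library for Figla (-0.0410 to 0.0309), Id3 (-0.0198 to 0.0354) and Smad6 (-0.128 to 0.0389), and with the GC and length trend removed for Id3 (-0.0158) and Figla (7.2e-04), none of them called. Of named-gene values, DESeq2 kept 402 and lost 24 calls, the GC and length correction kept 413 and size factors kept 426. Of all main calls, the GC and length correction kept 2047 of 2239 for BMP2 against vehicle. It kept 4577 of 5278 for E2 against vehicle and 4098 of 4607 for BMP2 against E2, with genes it could not cover counted as lost. In simulated counts, 1.1-fold changes were recovered in 38% of cases. That simulation changed only 200 genes, so the share need not hold for the real comparisons.

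With the replicate number as a block, 1252 and 1260, 2705 and 2807, and 2442 and 2433 genes were higher and lower, against 1119 and 1120, 2577 and 2701, and 2310 and 2297 without it, 1602 were called in both (1395 without), and 7, 14 and 11 lists passed; 2236, 5272 and 4605 of the main calls were among those. With group means removed, correlations of libraries with the same number were -0.0311 to 0.0271, and 4 of 9 libraries correlated best with their own number. Whether the numbers mark a shared litter or day is not known. The block ended the calls of 3 of 34 passing lists (oocyte genes for BMP2 against vehicle, adjusted p 0.0703, the stress response for E2 against vehicle, 0.0529, and pericytes for BMP2 against E2, 0.0565) and of no named gene. It added the calls of Esr1 with E2 (0.0494) and of Sohlh1 for BMP2 against E2 (0.0205). For BMP2 against E2, 11 lists passed with and without the block, so another list passed in place of pericytes. The cause was not tested.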

Other observations

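All tests here on lists of piRNA, imprinted, ribosomal protein and granule genes were chosen only after values were seen. Of 20 genes of the piRNA pathway, which silences transposons in the germ line, 8 rose with BMP2 (adjusted p = 2.6e-09, and adjusted p = 0.00572 with an estimated correlation) and 9 with E2 (adjusted p = 2.2e-05, and adjusted p = 0.0353 with an estimated correlation). Piwil2, an Argonaute-family protein of this pathway, had log2 fold changes of 0.38 and 0.44 with BMP2 and E2, and Tdrd9 of 0.51 and 0.62. Of 76 ribosomal protein genes, 65 fell with BMP2 and 66 with E2, by medians of -0.14 and -0.12. Adjusted p was 8.2e-36 and 3.1e-16, and 0.0112 and 0.0611 with an estimated correlation. With the GC and length trend removed, 63 and 55 fell, at medians of -0.11 and -0.087. Between BMP2 and E2, 1 ribosomal protein gene was higher with BMP2, 13 were lower and 62 did not pass (median -0.026). That list gave adjusted p = 0.0429, but 0.528 with an estimated correlation. Of the piRNA genes, 2 were lower with BMP2 than with E2 and 18 did not pass (median -0.0064, adjusted p = 0.414). Both comparisons used the same vehicle libraries, so vehicle libraries that differed cannot be told apart from a like effect of both treatments.

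Of 18 imprinted growth genes, 5 rose and 9 fell with E2 (adjusted p = 0.0178, but adjusted p = 0.0611 with an estimated correlation), and with BMP2 2 rose and 4 fell (adjusted p = 0.0696). H19 had log2 fold changes of 0.045 and -0.55 with BMP2 and E2, Mest of -0.10 and -0.35, and Igf2, of which a same-strand gene covers 62.8%, of -0.0031 and -0.50. The retinoid list did not pass with E2 (adjusted p = 0.302), where 3 rose, 5 fell and 3 did not pass (adjusted over the list alone, 3 rose and 5 fell) of 11, with Crabp1 at -0.95, Stra6 at -0.63 and Aldh1a2 at 0.50. Stfa1 had 1 count in all E2 libraries together, 130 with vehicle and 360 with BMP2. The ratio of BMP2 to E2 was 332 (95% exact Poisson interval 59.2 to 13153), for counting error only, and reads of this paralog family are uncertain.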
